A study of Rattus norvegicus with 36 samples.

How the data were processed

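Messenger RNA of the nucleus accumbens, a ventral striatal region of the brain's reward circuit, was measured by RNA sequencing in 9 Sprague-Dawley rats aged 8 weeks. Conditioned place preference pairs a drug with one of a pair of compartments and later records where the animal spends its time. Per the labels' protocols, conditioning used cocaine at 20 mg/kg given intraperitoneally, with sessions of 20 min set 6 h apart, and the treatment label counts 4 cocaine injections. Control rats received saline on the same schedule, and the test of preference took place on the day after the last session. The labels place 3 rats in each of 3 groups, Vulnerable, Non Vulnerable and Saline, and give 4 technical replicates, a to d, for every rat, 36 libraries in all. The series description speaks of rats that expressed the preference, rats that did not, and saline rats. No sample label states that Vulnerable means having expressed it, so the groups are named here by the phenotype label. The tissue label names the nucleus accumbens, while the extraction protocol also mentions the caudate putamen; how far a sample holds dorsal striatum is not given in the sources used here.

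Libraries were made from polyA-selected RNA with a strand-specific kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR without a version, and HTSeq 0.5.3. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could have been assigned in more than one way. The authors deposited whole-number read counts per Ensembl gene ID, not normalized, in one table per library, with no row for unassigned reads. Each table held 31546 gene IDs, and 8585 of them had 0 counts in all 9 rats. The files do not pair the IDs with gene names, and the RefSeq gene table of assembly GRCr8 used here paired 0 of the IDs with a symbol. Gene names are therefore not reported, and at most 2 IDs per direction are printed for a comparison. For the same reason 34 gene lists fixed before the data were examined (signalling pathways, neighbouring regions, cell types and signs of tissue quality) could not be matched. The planned list tests, the marker checks of cell types and regions, and checks of gene length or GC content were void, because 0 of the members had a value.

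The technical replicates of each rat were compared by chi-square over genes with at least 40 counts in the rat. The statistic per degree of freedom lay between 1.004 and 1.02, the value of sampling noise, and no libraries were identical. Between rats of a group it was 51.8 (Vulnerable), 52.05 (Saline) and 118.4 (Non Vulnerable). The 4 libraries of a rat were summed and counted as 1 sample, so n = 3 per group. The labels number the rats within each group, and the rats are taken as separate animals on that basis.

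Summed counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (16029 genes), scaled with TMM and fitted with glmQLFit (robust) over all 9 rats, with a coefficient per group and 6 residual degrees of freedom. This fit gives a gene the same spread in all 3 groups, although the chi-square between rats was largest in the Non Vulnerable group. P-values of comparisons with Non Vulnerable rats rest on that assumption. Contrasts compared Vulnerable with Non Vulnerable, each of these with Saline, and the mean of both cocaine groups with Saline; a further test asked for any difference among the 3 groups. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes came from the quasi-likelihood F statistic. Levels are CPM, that is, counts scaled to a common total with TMM-scaled library sizes, and log2 CPM used a prior count of 2. The chance share of genes whose groups do not overlap is 10% for 3 rats against 3. It is an average over groupings, and genes that move together can put a single grouping far from it. Called genes are picked on the same rats, so their lack of overlap adds no separate support. An exact two-sided rank or permutation test of a single gene cannot go below p = 0.1 for 3 rats against 3. IDs named for a comparison are, by a rule set before the data were examined, the called genes of largest rise and fall with non-overlapping groups. Where few or no genes were called, they are the genes of smallest p, given as values.

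The procedure was tested on simulated counts drawn from the real means, spreads and library sizes, with 200 genes changed. For Vulnerable against Non Vulnerable (15863 genes), 24% of 50 genes changed 1.5-fold, 52% of those changed 2-fold and 84% of those changed 3-fold were called. For Vulnerable against Saline (15862 genes) the shares were 38%, 62% and 80%, and for Non Vulnerable against Saline (15877 genes) 26%, 78% and 80%. False calls numbered 4 of 126, 3 of 131 and 4 of 143. Alternatives fixed before the data were examined were median-of-ratios size factors, DESeq2 1.42.0, limma 3.58.1 voom, no filter or a strict filter on low counts (at least 1 CPM in 3 rats and a mean of 50 counts), a non-robust spread, only the compared groups, the rat number as a block, 1 technical replicate, 36 libraries as independent, and leaving out each rat. Alternatives chosen after seeing the data were thinning of counts, removal of the 10 most counted genes, a residual principal component as covariate, and quantile normalization before voom. Applying alternatives, leaving out rats included, to the counts at 1.5-fold or more was also decided after seeing the data. Where comparisons shared a group of rats, unchanged groups were simulated 20 times. This gave the correlation that sharing alone produces when every gene varies independently between rats. Variation that moves many genes of a rat together was not simulated. Plots were drawn with matplotlib 3.10.9.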

Results

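Nucleus accumbens transcriptomes were compared among 3 Vulnerable and 3 Non Vulnerable rats conditioned with cocaine and 3 rats given saline. Total counts per rat, summed over 4 technical replicates, were 47787001, 52189554 and 64081679 in Vulnerable rats 1 to 3. They were 50210925, 41213813 and 44461324 in Saline rats, and 50157802, 49633019 and 42017373 in Non Vulnerable rats. Technical replicates of a rat differed by no more than the sampling noise and were counted as 1 sample. Between 19331 and 20105 gene IDs had at least 1 count in a rat. The 10 most counted genes took 10.5% to 13.3% of the counts in 8 rats and 18.2% in Non Vulnerable rat 1. Gene IDs are given as the files hold them, which do not pair them with gene names.

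The 3 Non Vulnerable rats lay apart from all 6 other rats on the first principal component of log2 CPM, which held 40.2% of the variance. Their scores were -7.51, -46.9 and -58.5, against 7.3, 10 and 9.22 for Saline rats and 30.5, 34.2 and 21.7 for Vulnerable rats. Non Vulnerable rat 1 lay nearer to the Saline rats than to its own group on this component. By root mean square log2 difference it was 0.38, 0.394 and 0.464 from Saline rats 1 to 3, and 0.426 and 0.527 from Non Vulnerable rats 2 and 3. Over all pairs this difference was 0.581 ± 0.0961 (SD, 9 pairs) for Non Vulnerable against Vulnerable rats and 0.482 ± 0.0638 (SD, 9 pairs) for Non Vulnerable against Saline rats. Saline and Vulnerable rats differed by 0.364 ± 0.0665 (SD, 9 pairs). Inside groups the differences were 0.358 ± 0.0799 (SD, 3 pairs) among Saline, 0.378 ± 0.106 among Vulnerable and 0.422 ± 0.107 among Non Vulnerable rats. Single pairs inside groups ran from 0.269 to 0.527. The means of Saline against Vulnerable and of Non Vulnerable against Saline rats both lay within that range. Only the mean of Non Vulnerable against Vulnerable rats lay above it. The second component, 18.5% of the variance, spread the Vulnerable rats from -43.9 to 34.9.

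**Figure D1:**
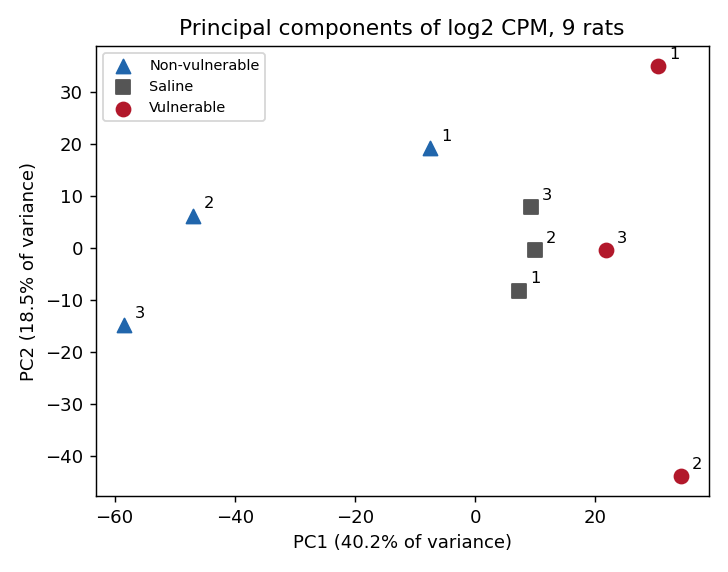
Scores of the 9 rats on the first and second principal components of log2 CPM, with the share of variance on each axis; numbers beside the points are rat numbers within a group. Non Vulnerable rats have first-component scores from -58.5 to -7.51, Saline rats from 7.3 to 10 and Vulnerable rats from 21.7 to 34.2.

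The comparison of Vulnerable with Non Vulnerable rats addressed what differed in the accumbens between rats given the same cocaine schedule; the series separates such rats by whether they came to prefer the drug-paired compartment. Levels differed for 5050 of 16029 genes tested (31.5%; edgeR, adjusted p under 0.05), of which 2419 were higher and 2631 lower in Vulnerable rats. Which direction held more genes depended on the setting: 2589 were higher and 2299 lower with median-of-ratios scaling, 2753 and 2109 without the 10 most counted genes, and 2300 and 1642 with only the compared groups in the fit. The changes were mostly modest, with a median absolute log2 fold change of 0.525 among called genes, or 1.44-fold, and a median SE of 0.144 over all genes. At least 1.5-fold differences were seen for 1230 genes higher and 935 lower in Vulnerable rats, and at least 2-fold differences for 436 and 328. Of the 764 genes that differed at least 2-fold, 529 (69.2%) had a mean of at least 1 CPM. Groups did not overlap for 7493 genes, or 46.7%, where chance gives 10% on average over groupings. Of the called genes, which were picked on the same rats, 4881 were among them.

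The largest differences of Vulnerable from Non Vulnerable rats belonged mostly to weakly expressed genes, with means under 1 CPM for all 10 genes of largest rise and 8 of the 10 of largest fall. ENSRNOG00000057734 had 11, 7 and 16 counts in Vulnerable rats and 0, 1 and 0 in Non Vulnerable rats, a ratio of 27 with an exact 95% counting interval of 4.52 to 1100 (edgeR adjusted p = 0.0121). ENSRNOG00000029141 stood at 0.828 ± 0.244 CPM in Vulnerable and 0.0938 ± 0.0472 CPM in Non Vulnerable rats (SD, n = 3), a log2 fold change of 3.08 with SE 0.632 (edgeR adjusted p = 0.00854). Of the genes lower in Vulnerable rats, ENSRNOG00000011207 had a log2 fold change of -6.23 with SE 1.84 (edgeR adjusted p = 0.0325), and rested on Non Vulnerable rat 2, with 1145 counts against 23 and 15 in the other Non Vulnerable rats. Without that rat its log2 fold change was -2.04 and its edgeR adjusted p 0.215, and its call also ended without Vulnerable rat 1, 2 or 3, with folds about as large (log2 -6.84, -5.70 and -6.31) and edgeR adjusted p of 0.0763 to 0.098. ENSRNOG00000007608 had 67 counts over the Non Vulnerable and 2 over the Vulnerable rats, a ratio of 42.2 with a counting interval of 11.2 to 356 (edgeR adjusted p = 0.0267). Its call ended without any one Vulnerable rat, Non Vulnerable rat 2 or Non Vulnerable rat 3, with log2 fold changes of -7.54 to -4.62 and edgeR adjusted p up to 0.0806. These intervals cover counting error only.

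The count of genes differing between Vulnerable and Non Vulnerable rats fell to 2820 without Vulnerable rat 2, 3050 without Vulnerable rat 3, 2798 without Non Vulnerable rat 2 and 3035 without Non Vulnerable rat 3. The split of higher and lower genes was 2449 and 1417 without Vulnerable rat 1, and 1943 and 1107 without Vulnerable rat 3. At 1.5-fold or more, the 1230 higher and 935 lower genes became 1319 and 558 without Vulnerable rat 1, 885 and 344 without Vulnerable rat 2, and 1115 and 469 without Vulnerable rat 3. They became 787 and 456 without Non Vulnerable rat 2, and 916 and 408 without Non Vulnerable rat 3.

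**Figure D2:**
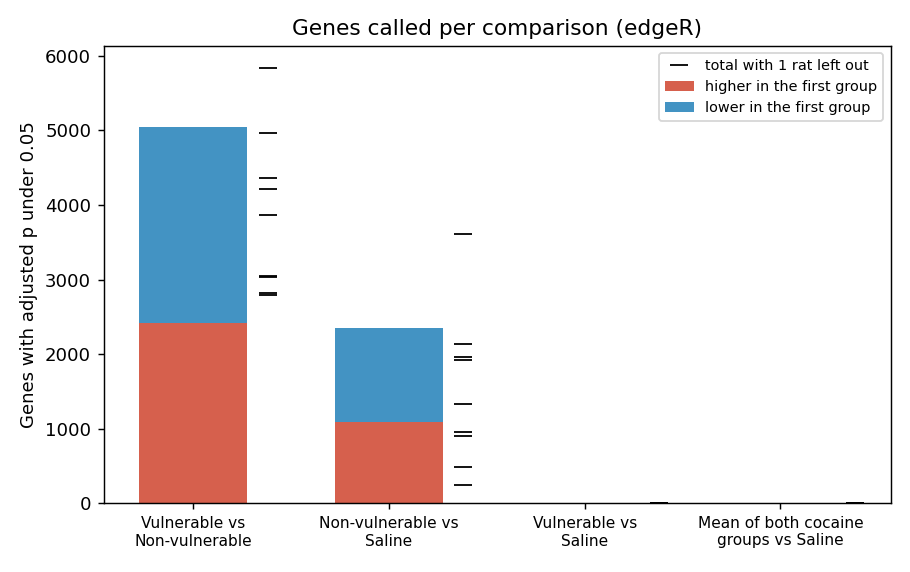
Number of genes with an edgeR adjusted p under 0.05 (vertical axis) in 4 comparisons; bars are split into genes higher and lower in the first group named, and black marks give the total after leaving out each of the 9 rats. Vulnerable against Non Vulnerable has 5050 genes and Non Vulnerable against Saline 2351, while both remaining comparisons have 0 with all rats and with any rat left out.

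Non Vulnerable rats also differed from Saline rats, which had the same handling without cocaine. The cocaine rats were divided by phenotype and the Saline rats were not. An effect of cocaine and one of that division cannot be told apart here or for Vulnerable against Saline rats. Levels differed for 2351 genes (14.7%; edgeR, adjusted p under 0.05), with 1091 higher and 1260 lower in Non Vulnerable rats, and the median change among them was 1.35-fold. By at least 1.5-fold, 131 genes were higher and 484 lower, and by at least 2-fold 32 and 123. The split at 1.5-fold depended on single rats, being 712 and 753 without Non Vulnerable rat 1. Without the 10 most counted genes, which moves the scaling between rats, the split of all calls was 663 higher and 1551 lower; without Saline rat 2 it was 28 and 223, and without Non Vulnerable rat 1 it was 1902 and 1713. Non-overlapping groups were found for 5605 genes (35%, chance 10%), 2333 of them called. Among weakly expressed genes, ENSRNOG00000036685 was higher in Non Vulnerable rats, 0.482 ± 0.344 against 0.0782 ± 0.0299 CPM (SD, n = 3), with log2 fold change 2.56, SE 0.625 and edgeR adjusted p = 0.0297. ENSRNOG00000032626 stood at 0.567 ± 0.229 against 0.126 ± 0.0787 CPM (SD, n = 3), with log2 fold change 2.18, SE 0.545 and edgeR adjusted p = 0.0323. ENSRNOG00000029141 was lower than in Saline rats, with log2 fold change -3.10, SE 0.635 and edgeR adjusted p = 0.0179. ENSRNOG00000057734 had 1 count over the Non Vulnerable rats against 23 over the Saline rats, a ratio of 22.3 with a counting interval of 3.62 to 918 (edgeR adjusted p = 0.0319).

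The number of genes differing between Non Vulnerable and Saline rats depended strongly on single rats. It was 251 without Saline rat 2, 490 without Non Vulnerable rat 2, 905 without Non Vulnerable rat 3, 952 without Saline rat 1, 1334 without Vulnerable rat 3 and 3615 without Non Vulnerable rat 1. At 1.5-fold or more, the 131 higher and 484 lower genes became 59 and 604 without Vulnerable rat 1, 33 and 456 without Vulnerable rat 3, 15 and 398 without Saline rat 1, and 5 and 127 without Saline rat 2. They became 20 and 154 without Non Vulnerable rat 2, and 16 and 295 without Non Vulnerable rat 3. ENSRNOG00000029141 lost its call without Non Vulnerable rat 2 or 3 (log2 fold changes -3.54 and -2.82, edgeR adjusted p up to 0.0616). ENSRNOG00000036685 kept its call only without Vulnerable rat 1 or 2 or Non Vulnerable rat 1, and ENSRNOG00000032626 only without Vulnerable rat 1 or 2 or Saline rat 3, of the 9 fits with a rat left out. ENSRNOG00000057734 kept it only without Vulnerable rat 1 or 2; adjusted p values of these 3 IDs in edgeR reached 0.115, 0.108 and 0.0926, while their fitted log2 fold changes, which for the last rest on 0 or 1 counts in Non Vulnerable rats, stayed at 1.92 to 2.96, 1.69 to 2.63 and -6.04 to -3.32.

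Vulnerable rats were not told apart from Saline rats gene by gene. With edgeR 0 genes were called, 807 had an unadjusted p under 0.05 where chance gives 801, and the smallest adjusted p was 0.309. That number rested on single rats, being 407 without Saline rat 1, 479 without Vulnerable rat 2 and 1517 without Saline rat 3. The limma voom fit called 0 and DESeq2 called 30 genes, 18 higher and 12 lower in Vulnerable rats. In simulated data for this comparison, 38% of genes changed 1.5-fold and 62% of genes changed 2-fold were called. Groups did not overlap for 1909 genes (11.9%, chance 10%). The smallest p belonged to ENSRNOG00000007607, at 61.7 ± 10.3 CPM in Vulnerable, 25.2 ± 2 in Saline and 33.5 ± 6.3 in Non Vulnerable rats (SD, n = 3). Its log2 fold change against Saline was 1.29 with SE 0.158, with edgeR adjusted p = 0.309 and 2.11e-09 in DESeq2; against Non Vulnerable rats it was higher by 0.88 on the log2 scale, with edgeR adjusted p = 0.00509. ENSRNOG00000015434 had a log2 fold change of 0.33 against Saline (SE 0.0563, edgeR adjusted p = 0.697). ENSRNOG00000025539 had a log2 fold change of -0.63 (SE 0.101, edgeR adjusted p = 0.697), with 23.6 ± 1.96 CPM in Vulnerable, 36.4 ± 1.94 in Saline and 47.3 ± 5.53 in Non Vulnerable rats (SD, n = 3). It was lower in Vulnerable than in Non Vulnerable rats, with edgeR adjusted p = 0.000886. ENSRNOG00000026907 had -1.55 against Saline (SE 0.241, edgeR adjusted p = 0.697). DESeq2 called all 4 of these IDs. Other alternatives read for them were median-of-ratios scaling, the rat number as a block and leaving out each rat. In these their edgeR adjusted p ranged up to 0.845 with all rats kept and up to 1 with a rat left out.

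The mean of both cocaine groups was also compared with Saline. A change in either group alone can move this mean and opposite changes cancel, so it does not isolate what the groups shared. With edgeR 0 genes were called, 1391 had an unadjusted p under 0.05 where chance gives 801, and the smallest adjusted p was 0.464. That number was 544 without Saline rat 2, 887 without Saline rat 1, 2105 without Non Vulnerable rat 1 and 2128 without Saline rat 3, so an excess over chance was not seen with every rat left out. The limma voom fit called 0 genes and DESeq2 called 110, 31 higher and 79 lower after cocaine. All 6 cocaine rats lay beyond all 3 Saline rats for 139 genes (0.867%), where chance gives 2.38%. ENSRNOG00000003977 was among them, with 45.8 ± 7.2 CPM in Non Vulnerable, 40.7 ± 8.19 in Vulnerable and 24.9 ± 3.31 in Saline rats (SD, n = 3), a log2 difference of 0.79 with SE 0.148 (edgeR adjusted p = 0.55). Against Saline it was called in Non Vulnerable rats (log2 0.88, edgeR adjusted p = 0.0139) but not in Vulnerable rats (log2 0.71, edgeR adjusted p = 0.897). For the mean of both groups, ENSRNOG00000007607 had a log2 difference of 0.85 (SE 0.14, edgeR adjusted p = 0.55). The smallest p values for a fall, in ENSRNOG00000008237 (log2 -0.48, edgeR adjusted p = 0.464) and ENSRNOG00000005124 (log2 -0.41, edgeR adjusted p = 0.464), came with overlapping groups. Both differed mainly in Non Vulnerable rats, where ENSRNOG00000008237 stood at 25.5 ± 1.15 CPM against 45.9 ± 3.13 in Saline and 42.8 ± 2.1 in Vulnerable rats (SD, n = 3). Non Vulnerable against Saline rats gave log2 -0.85 for it (edgeR adjusted p = 0.00571), and -0.65 for ENSRNOG00000005124 (edgeR adjusted p = 0.00571).

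**Figure D3:**
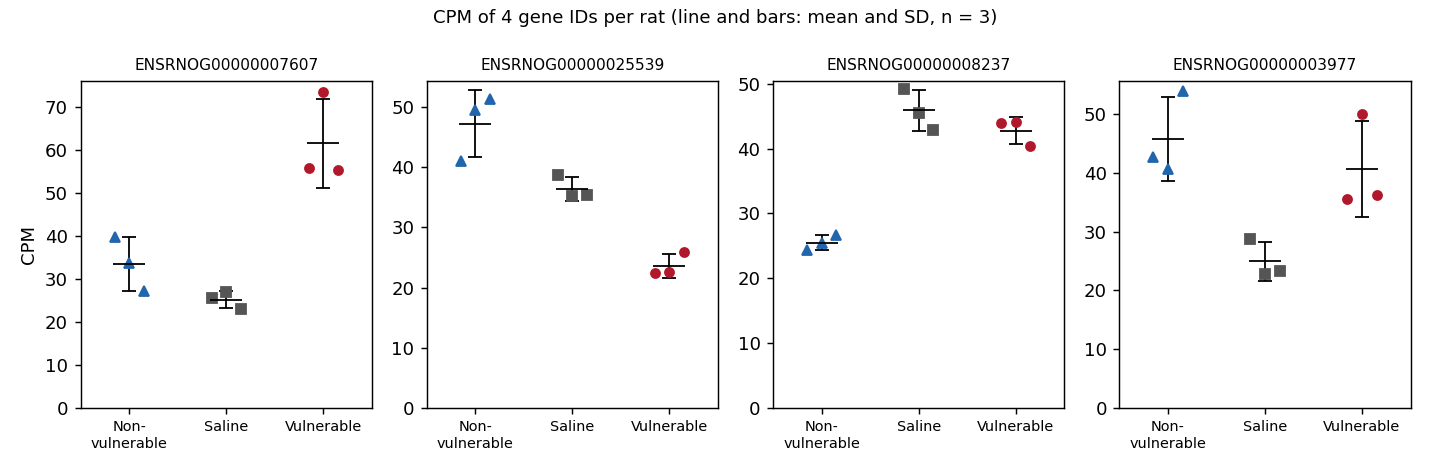
CPM (vertical axes, from 0) of 4 gene IDs in each rat, by group; symbols are rats, and the horizontal line with bars is the mean and SD of 3 rats. ENSRNOG00000008237 has 25.5 CPM in Non Vulnerable rats against 45.9 in Saline and 42.8 in Vulnerable rats, and ENSRNOG00000025539 runs from 47.3 in Non Vulnerable through 36.4 in Saline to 23.6 CPM in Vulnerable rats.

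Tested for any difference among the 3 groups, 3416 genes were called (21.3%; edgeR, adjusted p under 0.05). Without 1 rat the count was 1969 (Vulnerable rat 2), 1818 (Vulnerable rat 3), 2150 (Saline rat 2), 1070 (Non Vulnerable rat 2) or 1438 (Non Vulnerable rat 3). Most genes that separated Non Vulnerable from Saline rats also separated Non Vulnerable from Vulnerable rats. Of genes higher in Vulnerable than Non Vulnerable rats, 1221 were also higher in Saline than Non Vulnerable rats (190 for independent lists), and 1031 genes were lower in both (179 for independent lists). No gene was called on opposite sides of Non Vulnerable rats, 2798 were called against Vulnerable rats only and 99 against Saline rats only. Both lists share the Non Vulnerable rats, so part of this overlap can come from those libraries.

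Across genes, the log2 fold changes of Vulnerable and of Saline rats from Non Vulnerable rats correlated at r = 0.87. Simulated unchanged groups gave 0.51 on average and at most 0.538. Genes are not independent replicates, yet the simulations drew each gene independently. The simulated values in this paragraph therefore do not bound what sharing gives where many genes shift together in a rat. The covariance was 0.237 against 0.0447 simulated, a difference of 0.192. The log2 fold changes of both cocaine groups from Saline correlated at r = -0.22, where simulated unchanged groups gave 0.502, with a covariance of -0.0303 against 0.0437. Signs were the same for 35.4% of genes, against 66.7% in the simulations. This correlation was 0.0927 without Saline rat 3 and 0.347 without a filter on low counts, while the Spearman correlation was -0.346, so its sign was not settled. Unchanged groups were not simulated without the filter or with a rat left out. The 3 Saline rats were too few to be split into parts that each keep a pair of rats.

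For the 5050 genes differing between Vulnerable and Non Vulnerable rats, the Saline mean was placed on a scale from 0 at the Non Vulnerable to 1 at the Vulnerable mean of log2 CPM. Its median position was 0.748, with quartiles of 0.622 and 0.872. Saline lay between both cocaine groups for 90.1% of these genes and nearer to Vulnerable rats for 89.1%. The median was 0.721, 0.823 and 0.717 for Saline rats 1 to 3 taken singly, 0.739 for genes higher in Vulnerable rats and 0.761 for genes lower in them. The genes were chosen for the difference between both cocaine groups, which favours positions between them.

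**Figure D4:**
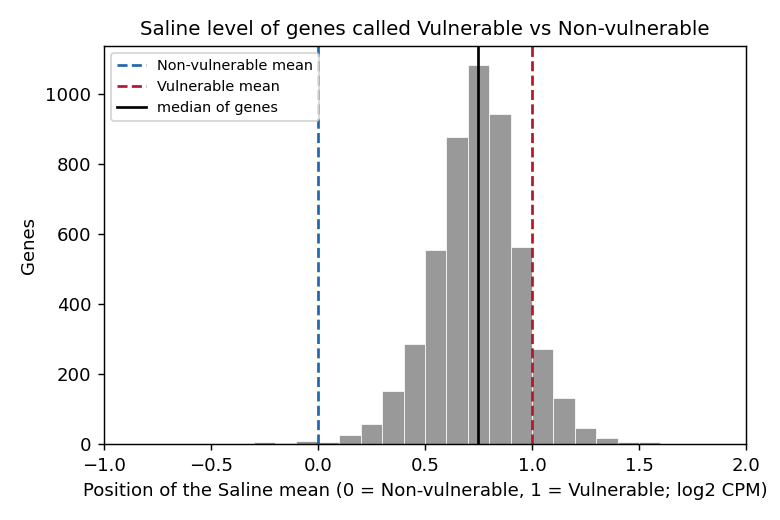
Histogram of the position of the Saline mean for 5050 genes that differed between Vulnerable and Non Vulnerable rats; the horizontal axis runs from the Non Vulnerable mean at 0 to the Vulnerable mean at 1 on the log2 CPM scale, and the vertical axis counts genes. The solid line is the median, 0.748, and 90.1% of genes lie between 0 and 1.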

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

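The departure from the shared Saline rats was not the same in Vulnerable and Non Vulnerable rats, by the test of the difference itself, with 5050 genes called. The Saline level cancels in that difference. The result is therefore the comparison of Vulnerable with Non Vulnerable rats given above, not a separate one, and does not measure an effect of cocaine. The tests on thinned counts, on the most counted genes, on quantile scaling and on differences within groups were chosen only after this result was seen, while median-of-ratios scaling was planned. Differences in depth between rats did not account for it: with every rat thinned to the shallowest total, 4993 genes were called. A few genes taking most of the counts did not either, since 4862 genes were called without the 10 most counted ones, nor did the scaling, since the lowest count under median-of-ratios or quantile scaling was 4570. An axis that also runs between rats of one group, such as RNA quality or dissection, stays open. Differences between rats inside the Vulnerable or Saline group were correlated with the fold between the groups not holding them. The median absolute correlation was 0.106 (0.00405 to 0.248 over 6 pairs). It lay between the bounds, which were set before this test was run but after the pattern was seen. The 3 Non Vulnerable pairs, not part of that test, gave 0.259, 0.301 and 0.153. All of them lay above the lower bound, and the largest passed the upper bound, which was set for a median. The sample numbers in the labels form 3 consecutive runs, one group in each, so a library batch following these numbers and the groups cannot be told apart, and a biological difference tied to the place preference stays open as untested.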

How the results depend on the processing

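Thinning, removal of the 10 most counted genes, the residual component and quantile scaling were chosen after seeing the data. So were all alternatives for the counts at 1.5-fold or more, for the Saline position and for the correlation sharing Non Vulnerable rats. The tests of gene lists were not run. Taking 36 libraries as independent called 10836 (Vulnerable against Non Vulnerable), 3197 (Vulnerable against Saline), 9053 (Non Vulnerable against Saline), 4189 (cocaine mean) and 11123 genes (any difference), since technical replicates hold no variation between rats. DESeq2 called 30, 3747, 110 and 5222 genes in the last 4 of these, and left 321 to 2807 adjusted p values undefined; the cause was not tested. Fitting only the compared groups called 1164 genes between Non Vulnerable and Saline rats. That fit had fewer rats to estimate the spread and did not use the spread of the Vulnerable rats. The cause of the lower count was not tested. The correlation of both cocaine groups' folds from Saline turned to 0.347 without a filter, and that of the folds from Non Vulnerable rats fell to 0.66; the cause was not tested. The other settings with all rats kept counts within 1.5 times, from 3942 to 6065 (DESeq2) for Vulnerable against Non Vulnerable, and kept 0 calls for Vulnerable and for the cocaine mean against Saline. Leaving out 1 rat gave 2798 to 5841 genes for Vulnerable against Non Vulnerable, 251 (without Saline rat 2) to 3615 for Non Vulnerable against Saline, 1070 to 4228 for any difference, and 0 to 0 for Vulnerable or the cocaine mean against Saline. It gave correlations of -0.27 to 0.0927 (without Saline rat 3) and 0.775 (without Saline rat 3) to 0.91, and Saline positions of 0.702 to 0.791. The share of calls higher in the first group moved from 46.4% to 29.9% for Non Vulnerable against Saline without the 10 most counted genes, to 25.6% with only the compared groups, and to between 11.2% (without Saline rat 2) and 52.6% (without Non Vulnerable rat 1) with 1 rat left out. For Vulnerable against Non Vulnerable it moved from 47.9% to 58.3% with only the compared groups and up to 63.7% (without Vulnerable rat 3). No scaling moved the median of all genes by over 0.1. No clear pairing of same-numbered rats was seen: deviations of 9 such pairs correlated at -0.137 to 0.19, 2 over 0.1, and 2 of 9 rats correlated best with their own number. With 3 rats per group these values cannot exclude a pairing. With the number as a block, 5160, 0, 2453, 0 and 3359 genes were called. The call of ENSRNOG00000011207 then ended with a smaller fold (log2 -4.17, edgeR adjusted p = 0.0893). That of ENSRNOG00000032626 ended with a fold about as large (log2 2.11, edgeR adjusted p = 0.0585). The named IDs were read only under median-of-ratios scaling, DESeq2, the block and the fits with a rat left out. Called and uncalled IDs together, 147 of these values kept direction and side of the threshold, 32 lost the call, 8 gained it and 0 changed sign. Many of the 147 were uncalled IDs that stayed uncalled, and all 32 losses fell on called IDs. All 8 gains were DESeq2 calls of IDs uncalled in edgeR. DESeq2 gave no adjusted p for ENSRNOG00000057734, ENSRNOG00000011207, ENSRNOG00000036685 and ENSRNOG00000032626, which were left out of this tally for DESeq2. Genes under 1 CPM carry few counts, and their folds are the least certain.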

Other observations

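Other groupings of the same rats were tested, as planned before their results were seen. The 6 Vulnerable and Non Vulnerable rats make 10 splits, too few for a share under 0.05: the real one called 5050 genes and the highest of the others 0, so 1 split called as many. For Non Vulnerable and Saline rats the real split called 2351 and the highest other 2, again 1 of 10 splits; for Vulnerable and Saline rats all 10 splits called 0. Of 100 drawn splits of the 9 rats into 3 groups, the real one included, 3 called at least the real 3416 genes for any difference, the highest other 4834. That share was under the 0.05 set beforehand, but it followed a structure of the samples. The 3 drawn splits that kept the Non Vulnerable rats together and mixed Vulnerable with Saline rats called 3171 to 4834 genes. The remaining splits called at most 4. The share thus comes from the Non Vulnerable rats standing together. It cannot single out the labelled grouping, nor tell it from a batch that follows the sample numbers. For the cocaine mean, whose real count was 0, all 100 splits called as many by construction, so they say nothing about chance; the highest other, 5869, again held the Non Vulnerable rats together.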
